A study of Homo sapiens with 40 samples.

How the data were processed

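RNA was extracted with a column kit, and gene counts were deposited for 40 libraries in 3 tables, one for the Jurkat knockdown, one for the knockdown labelled HPB-ALL and one for 6 untreated lines. Per the labels, Jurkat cells received siRNA by electroporation and their RNA is described as total RNA, the cells labelled HPB-ALL were infected with virus by centrifugation, and the RNA of these and of the untreated lines is described as polyadenylated. Medium held 20% serum for HPB-ALL and KARPAS-45 and 10% for the other lines. The labels name a stranded messenger RNA kit for the cells labelled HPB-ALL; how the other libraries were prepared is not given in the sources used here. The deposited values are raw read counts per gene, in whole numbers. The tools and build named for them, per the submitters' processing notes, are Trimmomatic 0.39 (read trimming), STAR 2.7.11b (alignment) and GRCh38. The counting tool, its strand setting and the annotation release are not given in the sources used here. All 3 tables list the same 62754 genes, of which 62700 were matched to a symbol. Gene positions were taken from GENCODE 29 on GRCh38. The table labelled HPB-ALL also holds totals that name no gene, 13.0% to 15.1% of all its reads (unmapped 3.80% to 4.40%, no feature 3.74% to 5.77%, ambiguous 5.13% to 5.32%), which were left out of library sizes and tests. Levels were set within each table, and levels compared across tables rest on separate normalizations.

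Groups, tests, gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where a choice is said to have been made later. The deposited counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, filterByExpr, TMM normalization, Benjamini-Hochberg adjustment, threshold 0.05). Each knockdown was fitted on its own 8 libraries. The difference between the knockdown effects was fitted in one model over 16 libraries and the genes passing the filter in both experiments. Its dispersion of each gene was shared by both experiments. The 24 libraries of the lines were fitted together, with an F test over all lines, a contrast of each line against the mean of the other 5 and the 15 pairs of lines for QKI. CPM were computed with the TMM factors, and the SE of a log2 fold change is its size over the square root of F. Standard errors, p-values and folds come from these fits unless another tool is named. A gene at 0 was set against a floor of 3 counts in each library.

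The 29 gene lists covered STAR family proteins, splicing regulators, transcripts tied to QKI elsewhere, lipid synthesis, stress responses, cell cycle, apoptosis, T-cell development, T-ALL oncogenes, migration, metabolism, and, as checks of composition, histone genes, mitochondrially encoded messenger RNAs and markers of B, myeloid, erythroid and megakaryocyte, and fibroblast or epithelial cells. Lists with at least 5 measured members were tested in the knockdowns with camera of limma 3.58.1 on voom values, with a preset correlation of 0.01 and again with an estimated one. Counts of called members are given over all genes and adjusted over the list alone. In each knockdown the text names QKI, the 12 largest rises and 12 largest falls among called genes with an average log2 CPM of at least 1, every knockdown library beyond every control and an ordinary gene symbol, and up to 4 called members of each list with the smallest p; not every list member that this rule picks is reported here. For both knockdowns it names up to 10 shared genes per direction, for the difference the 6 with the smallest p per direction, and for each line the 5 with the largest fold among genes above all other lines, with members of the lists on T-ALL transcription factors, thymocyte stages and immature markers. Genes named outside this rule, such as the Jurkat genes called with the block, further MHC genes, lineage genes such as ELANE and CD3E, neighbours of QKI and other list members in the lines, were chosen after their values were seen.

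Replicate numbers are shared across groups. In Jurkat the same-numbered control and QKI siRNA libraries deviated from their group means together (correlations 0.733 to 0.877), and 8 of 8 libraries correlated best with their own number, so the numbers pair these libraries, although the labels do not say what they share. The fit with the number as a block is given beside the Jurkat results it changes. In the libraries labelled HPB-ALL the numbers did not pair the libraries. In the lines same-number correlations ran from -0.216 to 0.548. They were not set against those of other numbers, so whether numbers pair the lines was not settled. A pair of LOUCY columns carry no number of their own and were used as replicates without one. No pair of replicates matched within counting noise: chi-square per degree of freedom over genes with at least 20 counts in the pair was 12.7 to 348.

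Alternatives were RLE size factors, no filter, DESeq2 1.42.0, limma-voom, a test against a fold of 1.2 (glmTreat), the replicate block and leaving out each library in turn. Counts were simulated with the means and library sizes of the real data. With no pairs simulated, the Jurkat test recovered 2 of 97 genes changed 1.5-fold and 26 of 94 changed 2-fold, over 20680 genes. With simulated pairs and the block it recovered 50 of 97 and 59 of 95, over 20628 genes. On the same simulated pairs without the block it recovered 0 of 97 and 12 of 95. The test for the libraries labelled HPB-ALL recovered 69 of 98 and 89 of 97, over 17781 genes, and the test of the difference 18 of 162 and 87 of 149, over 15442 genes. A line against the other 5 was recovered in 43 of 92 and 67 of 95, and any difference among the lines in 22 of 92 and 49 of 95, over 19186 genes. False calls numbered 3 in Jurkat with no pairs simulated, 9 with simulated pairs and the block, and 0 on those pairs without the block. They numbered 8 for the libraries labelled HPB-ALL, 13 for the difference, 5 for a line against the others and 6 for any difference. Their share of all calls passed the threshold in Jurkat with no pairs simulated and with the block. It also did for the difference and for any difference among the lines. Splicing was not analysed here.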

Results

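QKI (quaking) is an RNA-binding protein of the STAR family that acts in splicing and in the stability of messenger RNA. It was studied here in T-cell acute lymphoblastic leukaemia (T-ALL), a cancer of immature T cells, by RNA sequencing of human cell lines. The data are read counts per gene for 40 libraries in 10 groups of 4 replicates. Jurkat cells, a widely used T-ALL line, received an siRNA against QKI or a non-targeting control (NTC) siRNA by electroporation. The count columns of this control are headed shNTC. They were taken as the control siRNA of the labels, since Jurkat has no other control group. Cells labelled HPB-ALL, another T-ALL line, carried a virus coding for a short hairpin RNA (shRNA) against QKI or a control shRNA. Untreated LOUCY, KARPAS-45, HPB-ALL, TALL-1, DND-41 and ALL-SIL made up the other 6 groups. The knockdowns address what depletion of QKI does to expression and splicing, and the 6 lines address how splicing varies with the amount of QKI. Splicing cannot be read from totals per gene and was not analysed here. The summed gene counts (M, 1e6 counts) ranged from 68.4 to 115.7 M in the Jurkat QKI siRNA libraries and from 103.8 to 134.2 M in their controls. They ranged from 119.8 to 134.9 M in the QKI shRNA libraries labelled HPB-ALL, from 81.0 to 127.1 M in their controls, and from 44.1 to 84.0 M in the untreated lines. The knockdown replicates are described as biological replicates. Nothing says that the replicates of the untreated lines came from separate cultures, so their p-values measure only the spread between these samples, which may be technical.

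QKI itself (ENSG00000112531.17, chromosome 6, 163414000 to 163578596 on the + strand of GRCh38) fell in both knockdowns. In Jurkat it went from 148 ± 19.5 CPM (counts per 1e6, scaled by TMM; mean ± SD, n = 4) with the control siRNA to 21.5 ± 4.22 with the QKI siRNA. The log2 fold change was -2.79 (SE 0.17, edgeR adjusted p = 0.000129). In the libraries labelled HPB-ALL it went from 104 ± 2.58 to 55.7 ± 1.42 CPM (SD, n = 4), a log2 fold change of -0.90 (SE 0.03, edgeR adjusted p = 1.1e-07). In both experiments all 4 knockdown libraries lay below all 4 controls. Among the untreated lines QKI was highest in TALL-1 (161.5 ± 4.24 CPM) and HPB-ALL (137.1 ± 19.7), followed by ALL-SIL (129.5 ± 11.5) and DND-41 (88.0 ± 5.54). KARPAS-45 held 6.70 ± 0.776 CPM (SD, n = 4). LOUCY had 0 QKI counts among 218.4 M counted reads in its 4 libraries. A count of 0 allows up to 3 counts, which is at most 0.0614 CPM in any 1 library; such floors cover counting error only.

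**Figure D1:**
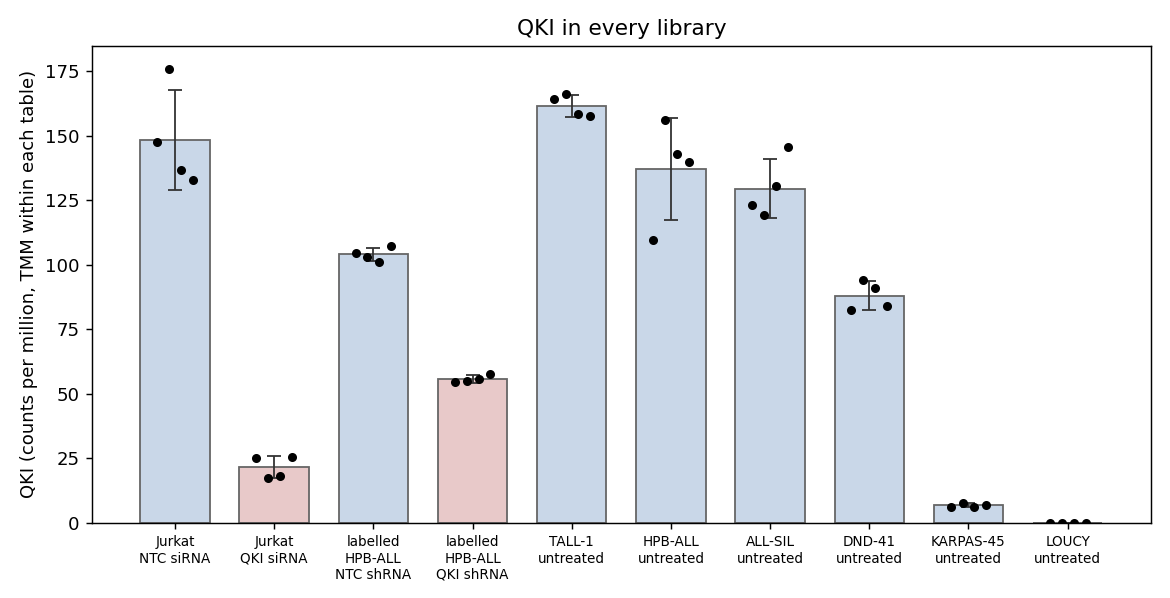
QKI level (CPM, linear axis from 0) in the 10 groups; bars are means, error bars the SD and points the 4 libraries of each group. QKI fell from 148 to 21.5 CPM in Jurkat and from 104 to 55.7 CPM in the libraries labelled HPB-ALL, and had 0 counts in LOUCY.

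Genes that mark untreated HPB-ALL were missing from the knockdown libraries labelled HPB-ALL. TLX3, a homeobox transcription factor, stood at 224 ± 58.7 CPM in untreated HPB-ALL (SD, n = 4) and had 0 counts in all 8 knockdown libraries. The T-cell receptor segments TRBV5-5 (866 ± 98.5 CPM) and TRAV5 (149 ± 14.6 CPM), which are fixed in the genome of a clonal T-cell line, also had 0 counts in all 8. CD3E, a chain of the T-cell receptor complex, averaged 924 CPM in untreated HPB-ALL and lay under 3 counts in every knockdown library. In the other direction the granule proteins ELANE and AZU1 and the lysozyme gene LYZ, 3 of 12 myeloid markers listed beforehand, were at or above 1580, 397 and 425 CPM in every knockdown library. In untreated HPB-ALL none of the 3 passed 0.232 CPM. CST3 was at or above 332 CPM in every knockdown library, against at most 32.1 in untreated HPB-ALL. ITGAM (76.8 against 0.620), FCER1G (23.2 against 0.232) and CSF1R (13.5 against 0.0187) were higher in the knockdown libraries too. Not all listed myeloid markers were high there: MPO, CD14, CD68 and S100A8 stood at 0.0553, 0.0582, 0.0151 and 0.151 CPM in the lowest knockdown library for each. Of 24 listed genes of the T-cell receptor complex and its signalling, 7 averaged over 1 CPM in the control shRNA libraries and 21 in untreated HPB-ALL. Across 15014 genes, which are not independent replicates, the control shRNA libraries had a Spearman correlation of 0.656 with untreated HPB-ALL and of 0.770 with LOUCY, the highest of the other lines. Control and knockdown libraries shared these features, so the comparison between them was kept, but the genes measured do not match the label. They are called the libraries labelled HPB-ALL throughout, and no result from them is read as one of untreated HPB-ALL.

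**Figure D2:**
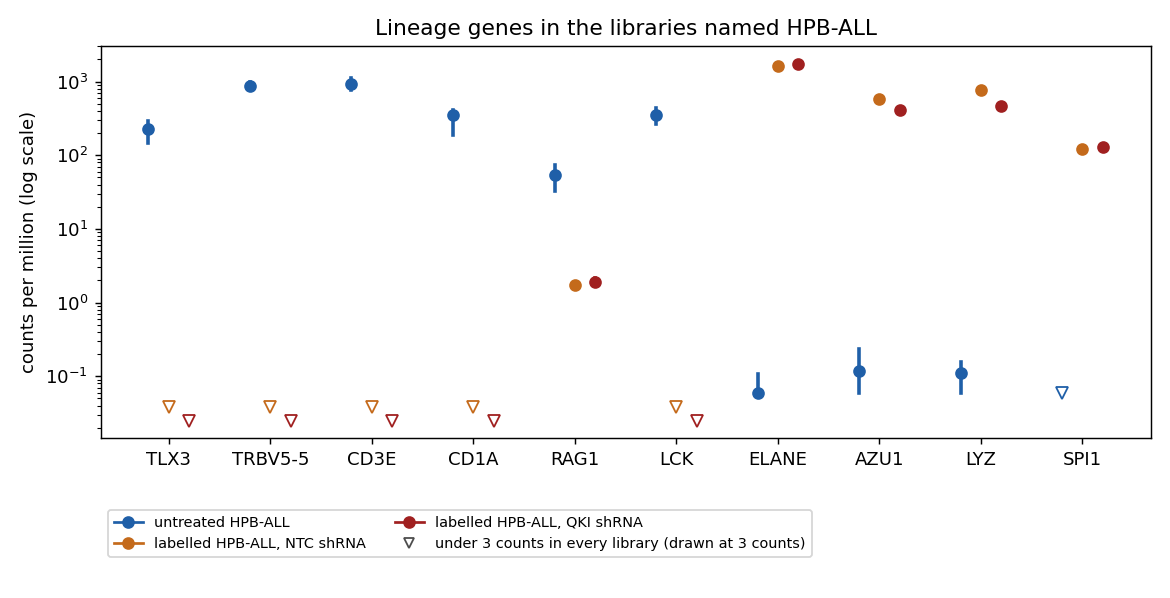
Levels of 10 genes (CPM, log axis) in untreated HPB-ALL and in the control and QKI shRNA libraries labelled HPB-ALL; points are means of 4 libraries, bars the range with its lower end held at the floor of 3 counts, and open triangles mark genes under 3 counts in every library. TLX3 and TRBV5-5, at 224 and 866 CPM in untreated HPB-ALL, had 0 counts in the knockdown libraries, where ELANE was at least 1580 CPM.

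In Jurkat, few genes besides QKI were called. The same-numbered control and knockdown libraries deviated together, and with the pair number in the model 9 of 21296 genes were called, 8 lower and 1 higher. The falling genes were QKI, GGCX (the vitamin K-dependent gamma-carboxylase), HOOK3 (a microtubule motor adaptor), UFC1 (the conjugating enzyme for the ubiquitin-like protein UFM1), MT-ND6 (a mitochondrially encoded subunit of respiratory complex I), CD3G (a chain of the T-cell receptor complex), ATP8A1 (a phospholipid flippase) and RBL1 (a relative of the retinoblastoma protein). FSD1L rose. Every one of the 9 moved in its direction in 4 of 4 pairs, which their selection by the fit to these same pairs favours. GGCX (chromosome 2, 85544723 to 85561547) went from 52.1 ± 3.63 to 29.7 ± 0.754 CPM (SD, n = 4), a log2 fold change of -0.81 with the pairs (SE 0.06, edgeR adjusted p = 0.000259). HOOK3 changed by -0.98 (SE 0.09, adjusted p = 0.000902), UFC1 by -0.80 (SE 0.08, adjusted p = 0.00177) and MT-ND6 by -0.82 (SE 0.09, adjusted p = 0.00409). CD3G went from 314 ± 31.8 to 219 ± 37.2 CPM, a change of -0.53 (SE 0.06, adjusted p = 0.00761). ATP8A1 changed by -0.47 (SE 0.06, adjusted p = 0.0146), RBL1 by -0.48 (SE 0.07, adjusted p = 0.0408) and FSD1L by 0.85 (SE 0.08, adjusted p = 0.000902). Without the pairs, edgeR called QKI alone, with 186 genes at an unadjusted p under 0.05 against 1416 with the pairs. The 8 genes besides QKI were therefore named after the pairing had been seen. With the pairs in the model and the arms of pair 3 swapped, edgeR called 11 genes, with 1500 at an unadjusted p under 0.05. Chance is thus not excluded for the count of 9. GGCX, HOOK3 and RBL1 overlap a gene on the opposite strand (MAT2A, RNF170 and an antisense transcript), FSD1L overlaps a pseudogene on its own strand, MT-ND6 is read from the strand opposite to the other mitochondrial messenger RNAs, and whether the counting used strand is not given. MAT2A and RNF170 changed by 0.00 and 0.05 with the pairs, and neither was called. CD3G, ATP8A1 and RBL1 lost the call without pair 1 (adjusted p = 0.230, 0.542 and 0.576) or pair 4 (0.0541, 0.238 and 0.0842), RBL1 also without pair 3 (0.0848), where 20 genes were called in all.

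**Figure D3:**
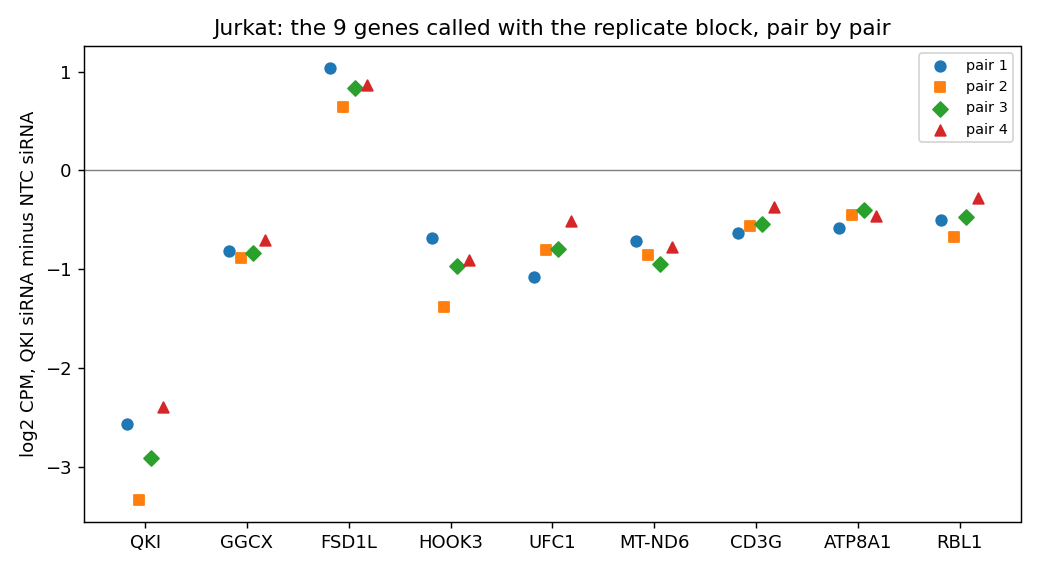
Log2 fold change (QKI siRNA minus control siRNA) of the 9 genes called in Jurkat with the pairs in the model, one point for each of the 4 numbered pairs. Every point of FSD1L lies above 0 and every point of the other 8 genes below it. The genes were chosen by the fit to these same pairs.

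Of the gene lists fixed beforehand, 25 had enough members for a test in Jurkat. Without the pairs, no member but QKI was called singly, over all genes or adjusted over the list alone. With the preset correlation, and not with an estimated one (adjusted p = 0.981 for each of the 4), the following moved as groups: S phase genes (42 members, median log2 fold change 0.10, camera adjusted p = 6.95e-05), nuclear-encoded oxidative phosphorylation genes (33 members, median 0.08, adjusted p = 0.00271) and histone genes (39 members, median 0.20, adjusted p = 0.000239) were higher, and mitochondrially encoded messenger RNAs (12 members, median -0.24, adjusted p = 0.000239) were lower. With the pairs, 8 lists were called: these 4 and, all higher, cholesterol synthesis (adjusted p = 0.00229), MYC targets (0.00602), the integrated stress response (0.0158) and G2 and M phase genes (0.0244). With the pairs and an estimated correlation, none held (adjusted p = 0.886 for each of the 8). Jurkat libraries carried far more histone counts than the others, 24017 ± 9501 CPM with the control siRNA and 27281 ± 13850 with the QKI siRNA (SD, n = 4) against 17 to 191 in every other library, and their RNA alone is labelled total RNA. The direction of the histone list turned without QKI siRNA library 2 (adjusted p = 0.0691) and without control library 4 (0.793), and the number of called lists was 1 without control library 1 and 7 without control library 2, 3 or 4. S phase genes lost the call without QKI siRNA library 2 (adjusted p = 0.192) or control library 1 (0.288), mitochondrially encoded genes without QKI siRNA library 3 (0.663) or control library 1 (0.0962), and oxidative phosphorylation genes without QKI siRNA library 2, 3 or 4 (0.192, 0.0795 and 0.195) or control library 1 or 2 (0.452 and 0.0746). The remaining lists were not called in either fit. Splicing regulators (65 members) had a median log2 fold change of -0.00, a mean of 0.00 and a test direction of up without the pairs and down with them (adjusted p = 0.815 and 0.889). T-ALL transcription factors had a negative median (-0.00) and mean (-0.03) and a test direction of up (adjusted p = 0.700). Transcripts described elsewhere as bound or regulated by QKI were at 0.03 (11 members, adjusted p = 0.933). The lists of interferon response, fatty acid synthesis, endoplasmic reticulum chaperones, heat shock, p53 targets, BCL2 family, NOTCH1 targets, T-cell receptor signalling, thymocyte stages, immature markers, immediate early genes, migration, hypoxia and B-cell markers had adjusted p from 0.263 to 0.990. STAR family proteins and the markers of myeloid, erythroid and fibroblast or epithelial cells had under 5 measured members and no test.

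In the libraries labelled HPB-ALL, 4175 of 17974 genes changed, 2299 higher and 1876 lower (edgeR), mostly by little: the median absolute log2 fold change of the called genes was 0.23. Only 8 rose and 66 fell by 2-fold or more. Among the genes named by rule, the falling ones included genes of major histocompatibility complex (MHC) class II, which presents peptides to helper T cells; these were not a list fixed beforehand and were not tested as a group. HLA-DRA went from 30.1 ± 3.66 to 9.42 ± 1.98 CPM (SD, n = 4), a log2 fold change of -1.68 (SE 0.14, adjusted p = 1.4e-05). HLA-DPA1 changed by -1.53 (SE 0.08), HLA-DRB5 by -1.25 (SE 0.08) and HLA-DRB1 by -1.24 (SE 0.06). CIITA, the transactivator of these genes, went from 18.7 ± 1.33 to 8.65 ± 0.486 CPM, a change of -1.11 (SE 0.06, adjusted p = 6.96e-07). Further genes of the class, looked up after these had been seen, fell too, such as CD74 (-0.65), its invariant chain, HLA-DPB1 (-1.51), HLA-DMB (-0.83) and HLA-DMA (-0.46). HLA-B (-0.28), HLA-C (-0.27) and B2M (-0.13), of class I, moved less, and RFX5, another factor at class II promoters, stood at -0.00 (adjusted p = 0.962). The other large falls were CD180 (-1.30), a receptor related to Toll-like receptors, SLC13A3 (-1.07), RIC3 (-1.02), F13A1 (-1.02), which codes for the A chain of coagulation factor XIII, NRXN3 (-0.87) and the long noncoding RNA SOCAR (-0.85). The 8 rises of 2-fold or more did not meet the set conditions on level, separation and symbol. Among genes that did, the largest rises were ITLN1 (0.99), CYBB (0.91, from 79.7 ± 5.39 to 149.7 ± 4.64 CPM), SLC5A10 (0.91) and TAS1R3 (0.90). CYBB codes for the catalytic subunit of the phagocyte NADPH oxidase. CD48 (0.72), the noncoding RNA SNHG1 (0.68), TULP3 (0.67), H2BC5 (0.66), MMP25 (0.65), the linker histone H1-2 (0.63), E2F2 (0.61), a cell cycle transcription factor, and PNMA6E (0.60) followed. Each of these 24 genes named by rule, QKI included, had all 4 knockdown libraries beyond all 4 controls. HLA genes share reads with near-identical copies, and CIITA, SLC5A10, TAS1R3, CD48, TULP3, H2BC5, MMP25, SLC13A3, RIC3, NRXN3 and SOCAR overlap expressed genes, so their values are uncertain where the counting split such reads. Against a fold of 1.2 (glmTreat), 284 genes were called.

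**Figure D4:**
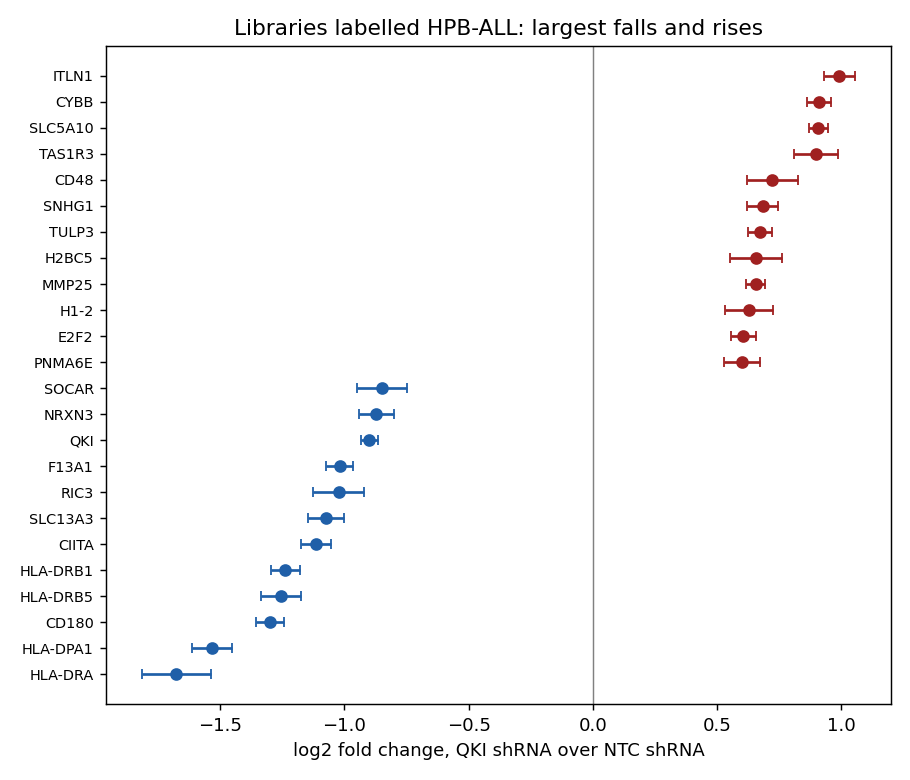
Log2 fold change (QKI shRNA minus control shRNA, n = 4 each) of the 24 genes named by rule in the libraries labelled HPB-ALL; points are edgeR estimates and bars the SE. Values run from -1.68 for HLA-DRA to 0.99 for ITLN1.

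Genes of cholesterol synthesis fell together in the libraries labelled HPB-ALL. Of 23 measured members 16 fell and none rose, or 18 fell adjusted over the list alone, with MSMO1 (-0.83), IDI1 (-0.36), DHCR7 (-0.32) and SC5D (-0.31) at the lowest p. Endoplasmic reticulum chaperones fell in 9 of 18 (11 adjusted over the list alone), among them PDIA4 (-0.35), MANF (-0.30) and HSP90B1 (-0.24). Heat shock genes fell in 5 of 14 (8 adjusted over the list alone), with DNAJA1 at -0.40 and HSPA1B, which has a near-identical copy, at -0.45. Oxidative phosphorylation genes fell in 5 of 33 (9 adjusted over the list alone), such as NDUFS1 (-0.20) and COX6C (-0.42). Genes of the G2 and M phases rose in 25 and fell in 3 of 50 (31 called adjusted over the list alone), led by HJURP (0.49), a centromere histone chaperone, NDC80 (0.49), a kinetochore protein, CDCA3 (0.46) and ANLN (0.35). S phase genes rose in 14 and fell in 1 of 42 (16 adjusted over the list alone), with EXO1 at 0.56, CCNE2 at 0.39 and RRM2 at 0.41. Of the transcripts described elsewhere as bound or regulated by QKI, 4 of 12 rose (MBP 0.24, ERBIN 0.24, CDKN1B 0.19 and FOXO1 0.21) and 1 fell (5 adjusted over the list alone). The camera adjusted p was 3.49e-10 for cholesterol synthesis, 4.6e-05 for the chaperones, 0.000398 for heat shock, 0.0117 for oxidative phosphorylation, 5.21e-07 for G2 and M, 0.0117 for S phase and 0.0258 for the transcripts tied to QKI. With an estimated correlation no list was called: the adjusted p = 0.589 for oxidative phosphorylation and S phase and 0.164 for the other 5. S phase genes also lost the call without control library 3 (adjusted p = 0.0797) and oxidative phosphorylation genes without control library 4 (0.0606).

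Listed markers of myeloid and B cells and of RNA composition moved with the QKI shRNA as well. LYZ, AZU1 and CST3 were high in every one of these libraries, so the fall of myeloid markers does not show other cells mixed in. Myeloid markers fell in 6 of 11 (7 adjusted over the list alone), with LYZ going from 758 ± 43.3 to 462 ± 27.3 CPM (SD, n = 4; log2 fold change -0.71) and AZU1 from 573 ± 11.4 to 413.5 ± 17.2 (-0.47); CST3 changed by -0.17 and S100A9 by -0.46. B-cell markers fell in 3 of 7 (5 adjusted over the list alone): CD22 (-0.53), CD24 (-0.30) and CD79A (-0.33), the last of which lost its call without control library 4 (adjusted p = 0.0628) or QKI shRNA library 4 (0.0636) and with the replicate block (0.0708). Histone genes rose in 9 of 17, also adjusted over the list alone, including H2AC6 (0.49) and H2BC11 (0.70), while histone counts in all went from 27.8 ± 1.29 to 37.6 ± 0.799 CPM. Mitochondrially encoded messenger RNAs fell in 4 of 12 (6 adjusted over the list alone), such as MT-ND5 (-0.35), and their share of counts went from 1.26% ± 0.173 to 1.05% ± 0.0576. MT-ND5 lost its call without control library 1 (adjusted p = 0.0505) or QKI shRNA library 2, 3 or 4 (0.0525, 0.0579 and 0.0628). The camera adjusted p was 0.00174, 0.0280, 4.62e-05 and 0.000926 for these 4 lists, and the adjusted p was 0.164, 0.164, 0.0751 and 0.457 with an estimated correlation. The B-cell list also lost its call without QKI shRNA library 2 (adjusted p = 0.0533) and with no filter on low counts (0.0640). Of 2 measured erythroid and megakaryocyte markers none was called, and of 3 fibroblast and epithelial markers PDGFRB was called (-0.28) but not without control library 3 or 4 (adjusted p = 0.0746 and 0.0813) or QKI shRNA library 1, 2 or 3 (0.0883, 0.0707 and 0.102), with no filter on low counts (0.0879) or with the replicate block (0.0707); both lists were too short for a test.

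The other lists were not called as groups, though single members passed. Migration and cytoskeleton genes had 9 lower and 3 higher of 32 (12 adjusted over the list alone; camera adjusted p = 0.0834), with ITGB7 at -1.18, ITGA6 at -0.31 and S1PR4 at 0.46. Targets of p53 had 6 higher and 3 lower of 19 (9 adjusted over the list alone; adjusted p = 0.0834), among them FAS (0.38), BTG2 (0.48) and MDM2 (0.18). Thymocyte stage markers had 7 higher and 2 lower of 19 (13 adjusted over the list alone; adjusted p = 0.148), with RUNX1 at 0.33 and CD38 at -0.33. Of 18 immature markers 4 rose and 5 fell (9 adjusted over the list alone; adjusted p = 0.479), including MN1 (-1.03), HOXA10 (-0.51) and LYL1 (0.23). T-ALL transcription factors had 3 higher and 2 lower of 12 (5 adjusted over the list alone; adjusted p = 0.340), with HOXA7 at 0.41 and LMO1 at -0.30. Splicing regulators had 7 higher and 4 lower of 62 (10 adjusted over the list alone; adjusted p = 0.479), among them RBM10 (0.33), SRSF4 (0.26), SRSF8 (0.20) and PTBP3 (-0.18). Fatty acid synthesis had 2 higher and 3 lower of 14 (6 adjusted over the list alone; adjusted p = 0.3901), with FADS1 at -0.37 and the desaturase SCD at -0.32. Interferon response had 4 higher and 7 lower of 35 (13 adjusted over the list alone; adjusted p = 0.514), such as SAMD9L (-0.44) and OAS2 (-0.52). The BCL2 family had 3 higher and 1 lower of 15 (4 adjusted over the list alone; adjusted p = 0.479), the lower one being BCL2 (-0.31). The integrated stress response had 3 higher and 2 lower of 27 (4 adjusted over the list alone; adjusted p = 0.703), MYC targets 2 higher and 3 lower of 30 (5; 0.591), and immediate early genes 4 higher and 2 lower of 26 (8; 0.703). NOTCH1 targets had 2 higher of 12 (2; 0.3901) and T-cell receptor signalling 2 higher of 12 (3; 0.479). Hypoxia and glycolysis genes had 5 higher and 3 lower of 25 (9; 0.896), with a median of -0.02, a mean of 0.01 and a test direction of up. Of 3 measured STAR family genes QKI alone was called.

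Between the experiments, QKI was the only one of 15730 genes tested in both that was called in both without the pairs, where independent lists would share 0.0994 lower genes. Of the Jurkat genes called with the pairs and measured in both, 4 of 7 lower genes were also lower in the libraries labelled HPB-ALL: QKI, HOOK3 (-0.50), ATP8A1 (-0.47) and RBL1 (-0.25), against 0.696 for independent lists. QKI is the target in both experiments, so its overlap, with or without the pairs, was fixed by design. FSD1L (0.16) was higher in both, against 0.137, and 0 genes were called in opposite directions. UFC1 (-0.20, adjusted p = 0.436), MT-ND6 (-0.35, adjusted p = 0.213) and GGCX (-0.01, adjusted p = 0.940) were not called there. Across all genes but QKI, which are not independent replicates, the fold changes had a Pearson r of 0.079, a Spearman rho of 0.035 and a covariance of 0.00416; over genes with an average log2 CPM of at least 3 in both, the Pearson r turned to -0.0389. Of 1225 joint relabellings of the arms, 540 gave an r of that size or larger, as did 93 of the 280 that part every numbered Jurkat pair.

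The knockdown effect itself differed between the experiments for 4 of 15730 genes, with 971 at an unadjusted p under 0.05 (edgeR). QKI fell further in Jurkat, by a difference in log2 fold change of -1.88 (SE 0.17, adjusted p = 0.000115). GGCX, called in Jurkat only with the pairs, was at -0.81 there and at -0.01 in the libraries labelled HPB-ALL, a difference of -0.79 (SE 0.10, adjusted p = 0.00650). TMTC3, a protein O-mannosyltransferase, was at 0.03 in Jurkat and at -0.75 in the libraries labelled HPB-ALL, a difference of 0.79 (SE 0.11, adjusted p = 0.00658). ERO1A, an oxidase of the endoplasmic reticulum that drives disulfide formation, was at 0.06 and -0.63, a difference of 0.71 (SE 0.10, adjusted p = 0.00658). With the pairs in the model 481 genes differed, the 4 among them, and without Jurkat QKI siRNA library 1 or 2 the count was 10 or 8. ERO1A lost its call without control library 2 labelled HPB-ALL (adjusted p = 0.0558), and with no filter on low counts both ERO1A (0.201) and TMTC3 (0.140) did. The model shared the dispersion of each gene between the experiments, although Jurkat varied more (square root of the common dispersion 0.322 against 0.0620). For TMTC3, ERO1A and GGCX the SE of the difference (0.108, 0.0968 and 0.102) was below the SE in Jurkat alone (0.114, 0.108 and 0.103). The SE and adjusted p of the differences are therefore likely too small. Cell source, delivery, the degree of depletion and the library protocol differ together between the experiments and cannot be separated.

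The 6 untreated lines differed in 19948 of 20348 genes tested (98.0%, edgeR). In QKI, 13 of the 15 pairs of lines differed. The exceptions were ALL-SIL with HPB-ALL (adjusted p = 0.531) and HPB-ALL with TALL-1 (adjusted p = 0.0632). Against the LOUCY floor of 3 counts per library, QKI was at least 98.5-fold higher in KARPAS-45 and at least 2569-fold higher in TALL-1. Against KARPAS-45 it was 13.1-fold higher in DND-41 and 24.1-fold higher in TALL-1. All 64 measured splicing regulators differed among the lines, 51 of them by 2-fold or more and 21 by 4-fold or more between the highest and lowest line, with a median of 2.75-fold. Against the mean of the other 5 lines, 42 were higher and 14 lower in KARPAS-45 (56 called adjusted over the list alone) and 28 higher and 8 lower in TALL-1 (36). In LOUCY 17 were higher and 24 lower (41), in ALL-SIL 15 and 5 (19), in DND-41 12 and 32 (44), and in HPB-ALL 6 and 33 (39). Because the QKI levels of the lines fall into separate clusters, no pooled correlation of QKI with these genes was computed.

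The lines differed in their leading genes. LOUCY differed from the mean of the other 5 in 13391 genes (7595 higher), led by the homeobox gene HOXB9 (294 ± 95.5 CPM; SD, n = 4), the receptor gene LILRA2 (165 ± 26.9), GCSAML (252 ± 32.6), the receptor segment TRAV23DV6 (629 ± 26.6) and MPST (146 ± 16.1), none of which passed 0.0491 CPM in another line. In LOUCY 14 of 17 immature markers were higher and 1 lower (15 called adjusted over the list alone), such as HHEX (175 CPM), ERG (151) and MEF2C (139), and 12 of 14 T-ALL transcription factors (12), among them LYL1 (279), HOXA10 (68.7) and LMO2 (32.2). Higher here means above the mean log level of the other 5, not above every line. These counts include genes scarce in LOUCY and far more abundant elsewhere. They are TLX1 (0.331 CPM, 391 in ALL-SIL), KIT (0.110, 8.68 in KARPAS-45) and BAALC (0.139, 39.1 in HPB-ALL). Of 32 thymocyte stage markers 19 were lower and 7 higher there (26), with CD1A at 0.419 CPM, CD4 at 0.490 and CD8A at 0.224, and 10 of 16 NOTCH1 targets were lower and 3 higher (13), with NOTCH3 at 0.158. B-cell markers were higher in 10 of 11 (10) and myeloid markers in 6 of 7, with 1 lower (7), while mitochondrially encoded genes were higher in 7 and lower in 1 of 13 (8) and histone genes higher in 12 and lower in 10 of 35 (22). KARPAS-45 differed in 14889 genes (7930 higher), led by FBLN1 (199 ± 25.7 CPM), an extracellular matrix protein, CRABP1 (72.3 ± 5.15), SCML2 (61.5 ± 2.79), PYGO1 (166 ± 4.99) and TRGV10 (198 ± 10.2). It held 137 CPM of the homeobox gene MEIS1 and 1070.1 of NOTCH3, and 37 of 42 S phase genes were higher and 1 lower (39) and 40 of 51 G2 and M phase genes higher and 4 lower (44), while 22 of 38 interferon genes were lower and 8 higher (31). Its libraries also stood apart in composition, with 1.01% mitochondrial messenger RNA counts against 3.78% to 7.11% on average in the other lines, and all 13 mitochondrially encoded genes were lower, while 16 of 35 histone genes were higher and 15 lower (31).

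HPB-ALL differed from the mean of the other lines in 12816 genes (8063 higher), with DOCK1 (444 ± 92.5 CPM), PON2 (54.0 ± 4.25) and SOCS6 (37.1 ± 5.69) beside TRBV5-5 and TRAV5, and 26 of 32 thymocyte stage markers were higher and 4 lower (30 adjusted over the list alone). There 12 of 35 histone genes were higher and 5 lower (16), 2 of 13 mitochondrially encoded genes higher and 5 lower (5), and 5 of 11 B-cell markers higher (5). TLX3 was found in HPB-ALL (224 CPM) and DND-41 (121 CPM). DND-41 differed in 11739 genes (6990 higher), led by ZNF677 (36.7 ± 2.73 CPM), MC5R (112 ± 33.0), HOXD13 (25.5 ± 6.91) and the receptor segments TRBJ1-6 (17.9 ± 2.90) and TRBJ1-5 (17.6 ± 2.27). It held 750.1 CPM of RAG1 and 127 of RAG2, the recombinase that assembles antigen receptor genes. ALL-SIL differed in 12046 genes (6870 higher), led by the homeobox gene TLX1 (391 ± 30.6 CPM), NRN1 (167 ± 23.4), ST8SIA2 (45.8 ± 8.70), KIF1A (69.5 ± 20.1) and the imprinted noncoding RNA H19 (1092 ± 256). Interferon genes were higher in 29 and lower in 5 of 38 in ALL-SIL (35) and higher in 28 and lower in 1 in DND-41 (29). Markers of RNA composition moved in the same lines: mitochondrially encoded genes were higher in 12 of 13 in ALL-SIL (12) and in 9 in DND-41 (9), and histone genes were lower in 18 and higher in 2 of 35 in ALL-SIL (20) and higher in 28 and lower in 1 in DND-41 (29). B-cell markers were higher in 7 and lower in 1 of 11 in DND-41 (8). TALL-1 differed in 11656 genes (6697 higher), led by TRAV8-4 (81.8 ± 22.8 CPM), ZCCHC14 (59.4 ± 6.58), NUDT11 (24.1 ± 1.76), the amino acid transporter SLC7A3 (37.9 ± 23.7) and AJAP1 (125 ± 13.2), which was also at 46.3 CPM in HPB-ALL. It held 264 CPM of DNTT, the terminal transferase of lymphoid precursors, and 104 of PTCRA, the pre-T-cell receptor alpha chain; 15 of 35 histone genes were higher and 3 lower there (18), and 5 of 13 mitochondrially encoded genes higher (5). TLX1, H19, HOXB9, PYGO1 and MPST overlap another expressed gene.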

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

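Leaving out both Jurkat libraries numbered 2 was chosen only after the result was seen. In 8 of 161 sets of 4 libraries, 1 library lay far from the other 3 (Dixon's test at its 95% critical value); chance does this in about 1 in 20 sets. Jurkat QKI siRNA library 2 held 48012 CPM of histone counts against 19452 to 21622 in the other 3, and the direction of the Jurkat histone list turned without it. Jurkat control library 3 had the highest total, 134.2 M against 103.8 to 108.4. In DND-41 library 4 the most abundant gene took 1.86% of counts against 2.40% to 2.48%. In the libraries labelled HPB-ALL, control library 3 was low in H1-2 (3.36 CPM against 4.67 to 4.82) and in HLA-DRB5 (5.10 against 5.84 to 5.97), and QKI shRNA library 4 was low in HLA-DRA (6.45 CPM against 10.3 to 10.6). TLX1 was at 346 CPM in ALL-SIL library 4 against 401 to 412, and SLC7A3 at 73.3 CPM in TALL-1 library 4 against 23.3 to 29.03.

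The knockdown effect differed between Jurkat and the libraries labelled HPB-ALL for 4 genes in a test of the difference itself: TMTC3 (0.79 on the log2 scale, Jurkat minus labelled HPB-ALL), ERO1A (0.71), QKI (-1.88) and GGCX (-0.79). That test shared the dispersion of each gene between the experiments, so its p-values are likely too small where Jurkat varied more. Of 50 drawn relabellings of the arms, the real one included, 3 gave 4 or more differing genes, and the highest of the others gave 168, so chance is not excluded for the count. That other count is many times the real one and points to a structure of the samples. Of 50 relabellings drawn after this was seen, with the Jurkat arms swapped only within numbered pairs, only the real one gave 4 or more, and the others gave 2 at most. Both sets also relabel the arms labelled HPB-ALL, so they break up the effects of both experiments. They cannot show how many genes would differ by chance if the effects were equal, and QKI, the target, is among the 4. No conclusion on chance is drawn from them. Without both Jurkat libraries numbered 2 the count was 13, with the 4 genes among them. No technical or biological explanation of these 4 differences was tested, since cell source, delivery and library protocol change together.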

How the results depend on the processing

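Versions of the block fit, leaving out a pair or both number 2 libraries in Jurkat, and leaving out KARPAS-45 were chosen only after seeing the data. QKI fell under every alternative, with log2 fold changes of -2.88 to -2.69 in Jurkat and -0.92 to -0.88 in the libraries labelled HPB-ALL. Jurkat genes numbered 1, 2 with DESeq2 and 9 with the replicate block; that block gave 37 genes with DESeq2 (the 9 kept) and 6 to 20 when a pair was left out (6 without pair 1, 20 without pair 3). Jurkat lists numbered 4, 8 with the block, 0 with an estimated correlation with or without the block, and 1 to 7 when a library was left out. The Jurkat histone list reversed without QKI siRNA library 2 and without control library 4, within adjusted p of 3.24e-13 to 0.793 over the libraries left out; its value without the former was 0.0691. In the libraries labelled HPB-ALL, 4175 genes became 284 against a fold of 1.2, 3063 with the block and 3132 to 3808 when a library was left out, and 11 lists became 0 with an estimated correlation and 10 to 12 when a library was left out. Their numbers did not pair the libraries (same-number correlations -0.206 to 0.036, 1 of 8 best with its own). In the lines same-number correlations ran from -0.216 to 0.548 and were not set against those of other numbers. Genes with a differing effect numbered 4, 102 with DESeq2, 481 with the block, 13 without both number 2 libraries and 3 to 10 when a library was left out (10 without Jurkat QKI siRNA library 1, 8 without library 2). The correlation of the effects was 0.079, -0.0389 over genes with an average log2 CPM of at least 3, and 0.0163 to 0.120 when a library was left out. Genes differing among the lines numbered 18319 to 26041, and pairs of lines differing in QKI 13 to 14 when a library was left out and 8 of 10 without KARPAS-45, where fewer pairs remain. The block moved no other count of calls by over 1.5 times. Of the named results under alternatives, 1474 of knockdown genes, 81 of differing genes, 49 of Jurkat genes with the block, 90 of line genes and 150 of called lists stayed past the threshold, and 73, 3, 7, 0 and 28 lost it in the same direction; the 2 reversals of the histone list lost it too. Counts of higher or lower genes stayed within 1.5 times in 51 cases and moved in 5: in Jurkat 2 lower with DESeq2, and 1 higher and 8 lower with the block; in the libraries labelled HPB-ALL 91 higher and 193 lower against a fold of 1.2. Apart from smaller tests and samples, the cause was not tested. The pooled correlation of QKI with splicing regulators and the knockdown signature across lines were not run, because the QKI levels of the lines form separate clusters and no gene besides QKI was called in both knockdowns without the pairs. Depth limits the absence of QKI in LOUCY to at most 0.0614 CPM in a library.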

Other observations

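The tests of a mixture, of the library kit, of reads lost in mapping, of a smaller loss at QKI and of the numbered Jurkat pairs were chosen only after the result was seen. LOUCY, which had 0 QKI counts, was the line with the highest level of KHDRBS3, another STAR family gene, at 29.5 ± 0.913 CPM (SD, n = 4) against 0.137 in KARPAS-45, 0.0461 in HPB-ALL and 0 counts in ALL-SIL, DND-41 and TALL-1; the gene was singled out after its values were seen. KHDRBS3 codes for a splicing regulator related to SAM68. LOUCY also held 53.9 CPM of SPI1 and 7.46 of CD33, genes of myeloid and early progenitor cells, and was the line with the largest number of higher endoplasmic reticulum chaperone genes (13 of 18, 1 lower; 14 called in all adjusted over the list alone) and cholesterol synthesis genes (18 of 24, 2 lower; 20). KARPAS-45 was higher in 20 and lower in 4 of 30 MYC targets (24) and higher in 11 and lower in 4 of 15 fatty acid synthesis genes (15). NOTCH3, a receptor and NOTCH1 target, was at 1070.1 CPM in KARPAS-45 and 799.5 in TALL-1 and at 0.158 in LOUCY.

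The libraries labelled HPB-ALL lacked TLX3, TRBV5-5 and TRAV5 and held some myeloid genes (4 of 12 listed markers over 100 CPM throughout). A mixture of HPB-ALL with other cells is argued against, since 3 counts of TLX3 allow at most 0.0168% of HPB-ALL in any library. The library kit or the counting is argued against as well, since 3 myeloid markers passed 100 CPM in all 8 libraries and stayed under 1 CPM in untreated HPB-ALL. A candidate explanation is another cell source or a wrong label in 1 of the tables: the receptor segments reached 0% of their untreated level in every library. The data do not tell which cells these are, and no biological explanation was tested.

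LOUCY had 0 QKI counts, which may reflect a silent gene or a lost one. Loss of the whole region within 3 Mb of QKI on every copy is argued against. There 5 measured neighbours, 2 before and 3 after QKI, were over 1 CPM in all LOUCY libraries. MAP3K4 was at 32.7 CPM and SFT2D1 at 26.8. The nearest of the 5 lay far from QKI, AGPAT4 2140 kb before it and SFT2D1 2741 kb after it, so they leave open a loss of several Mb between them. Reads lost in mapping or counting are argued against by the other lines, whose lowest QKI count was 407. A smaller loss between AGPAT4 and SFT2D1 cannot be told apart from silencing: the 2 measured neighbours there, CAHM and PDE10A, were under 3 counts in LOUCY, but CAHM also had 0 counts in KARPAS-45, which has QKI. Loss of 1 copy was not tested.

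Few genes were called in Jurkat although QKI fell further than in the libraries labelled HPB-ALL. Differences between the numbered pairs are a candidate for part of it: the square root of the common dispersion was 0.322 without the block and 0.130 with it, a ratio of 2.47, against 0.0620 in the libraries labelled HPB-ALL. As the whole cause they are argued against, since the calls rose only from 1 to 9 with the pairs fitted, 0.216% of the 4175 in the libraries labelled HPB-ALL; this test was chosen after the result was seen. Sequencing depth is argued against by the totals themselves, 68.4 to 134.2 M in Jurkat and 81.0 to 134.9 M in the libraries labelled HPB-ALL. Thinned to the Jurkat totals, the latter kept 98.7% of their number of calls (4122 of 4175, 3943 shared). Since the totals were close to begin with, the thinning could hardly lose most calls and adds little. With the pairs fitted, 1 called gene was higher and 5 lower by 1.5-fold or more, against 79 and 301 in the libraries labelled HPB-ALL. A weaker response of Jurkat cells to the loss of QKI stays open, since cell source, delivery and library protocol differ together.

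Other splits of the same samples show where chance can be excluded. In Jurkat, 2 of 35 splits into 4 and 4 called as many genes as the real one, which called 1; the other called 7623 and set numbers 1 and 2 against 3 and 4, which points to a structure of the samples. For Jurkat lists 30 of 35 splits called 4 or more, with 16 at most, so chance is not excluded. Among the 8 splits that part every pair, as the real one does, the others called 0 genes and 3 to 9 lists. With the pairs, 2 of 8 swaps of the arms called 9 or more genes (11 in the other), and these swaps are too few for a share under 0.05. In the libraries labelled HPB-ALL chance is excluded for genes (1 of 35 splits, 4175 against 0 at most in the others). For lists with the preset correlation the real split also gave the most (1 of 35), but by 11 against 10. That margin does not exclude chance for any single list, and no list was called with an estimated correlation. Chance is not excluded for the correlation of the effects (540 of 1225 relabellings, 0.079 against 0.375 at most). Nor is it among the 280 relabellings that part every Jurkat pair (93, with 0.156 at most). Among the lines, shuffled labels break up the replicates, which may be technical, so the real labels could hardly give fewer calls. No conclusion on chance is drawn from this. The real labels gave the most calls for genes differing at all (1 of 30 relabellings, 19948 against 316 at most). They also did for pairs differing in QKI (13 against 0) and for each line against the others. There the real count and the highest other one were 12046 and 3560 in ALL-SIL, 11739 and 25 in DND-41, 12816 and 3299 in HPB-ALL, 14889 and 3409 in KARPAS-45, 13391 and 159 in LOUCY, and 11656 and 2073 in TALL-1.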
